A study of Homo sapiens with 8 samples.

How the data were processed

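Bulk RNA sequencing of DOHH2 cells was analysed for 8 libraries: 3 of solvent controls, 2 of cells given 25 nM TSN and 3 of cells given 50 nM TSN, all after 24 h. Per the labels' protocols, RNA was extracted with Magzol and its integrity was read on a Bioanalyzer before libraries were made. Per the submitters' processing notes, reads were trimmed with fastp, aligned with HISAT2 (version 2.0.5), and the deposited counts per gene were made with featureCounts (version 1.5.0-p3); DESeq was named for their own testing. The genome build, the annotation and the strand setting are not given in the sources used here, so no coordinates are printed. The deposited table held whole-number counts for 35027 gene symbols, of which 14377 had no count in any library.

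From these counts, genes were kept with filterByExpr on the groups, which left 13064 genes, 11569 of them protein-coding. Libraries were scaled by TMM, and all 8 were fitted together with the quasi-likelihood F-test of edgeR (version 4.0.16, R 4.3.3). The common dispersion was 0.00344, a biological coefficient of variation of 5.87%. The contrasts tested were 50 nM against control, 25 nM against control and 50 nM against 25 nM. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05, and calls with more than 2-fold change are counted separately. The SE of a log2 fold change is its size over the square root of F.

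Genes were named by a rule written before the data were examined: protein-coding, called, more than 2-fold, a mean of at least 5 CPM, and every treated library on the same side of every control library. The 8 largest changes and the 4 most abundant genes per direction were taken, for 50 nM against 25 nM the 5 largest per direction without a fold limit, and for each list up to 4 members with the smallest adjusted p at 50 nM. MYC, BCL2, BCL6, CDKN1A and MKI67 were always reported. The contrasts, the tests, 31 gene lists with 691 distinct genes and the alternatives were also chosen before the data were examined, except for a length and GC correction. Lists were tested with camera (limma version 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry, each adjusted over the lists of a contrast. List members were also counted with p adjusted over the list alone.

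Alternatives were DESeq2 (version 1.42.0), DESeq2 size factors, total-count scaling, no filter and a filter at a mean of 5 CPM. Others were only the libraries of the groups compared, the replicate number as a block, and each library left out in turn. Leaving out a 25 nM library left 1 at that dose, so the spread then came from the other groups. DESeq2 gave no adjusted p to 1269 of the 13064 genes at 50 nM, 2788 at 25 nM and 6079 between doses. These were counted as not called. From each library the length and GC correction removed a spline trend (4 degrees of freedom) on transcript length and GC content. The trend was fitted to log2 CPM less the gene's mean over all libraries. Length and GC content were known for 97.5% of the genes. The overlap between doses was set against 50 simulations of unchanged groups that share their controls. The shares of mitochondrial counts were compared by exact permutation.

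The fit was tested on simulated data in which 200 genes had a known change, with the spread estimated from these libraries. Each real contrast called more genes than that, so the rates below need not hold for the real contrasts. At a true log2 change of 1 it recovered 82% of changed genes for 50 nM against control, 77.55% for 25 nM and 80.81% between doses; at 0.5 it recovered 76.53%, 65.66% and 74.49%. Of the calls in these simulations 4.85%, 6% and 8.38% were false. Python (version 3.11.15) and matplotlib (version 3.10.9) drew the figures. No library was left out, and reads were not analysed here.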

Results

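RNA was sequenced from DOHH2 cells, a human B-cell lymphoma line that the labels class as diffuse large B-cell lymphoma, after 24 h with toosendanin (TSN), a limonoid triterpenoid from Melia trees, or with its solvent. Gene counts were analysed for 3 solvent control libraries, 2 libraries at 25 nM and 3 libraries at 50 nM. The counts assigned to genes came to between 15891201 and 16783861 per control library, to 15877977 and 14402695 at 25 nM, and to between 14063455 and 15396908 at 50 nM. Libraries of one group differed by more than counting noise, with a variance of 2.45 to 11.6 times the Poisson value, so none was treated as a duplicate. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Below, changes are log2 fold changes ± SE, and a gene was called when its adjusted p from edgeR's quasi-likelihood test was under 0.05.

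The first comparison asked which transcripts differed between cells given 50 nM TSN and solvent (n = 3 libraries in each group). Transcripts for glycolysis under low oxygen and for sterol synthesis were higher, and transcripts for mitosis were lower. ALDOC, an aldolase of glycolysis, rose from 11.2 ± 1.75 to 50.4 ± 1.18 CPM (mean ± SD, n = 3), a fold of 4.5 (2.17 ± 0.11, adjusted p = 2.74e-12). PFKFB4, a bifunctional enzyme that sets the level of the glycolytic activator fructose 2,6-bisphosphate, rose 4.23-fold (2.08 ± 0.08, adjusted p = 8.5e-14). INSIG1, which holds back the SREBP precursors in the endoplasmic reticulum, rose 2.08-fold (1.06 ± 0.06, adjusted p = 1.39e-11). CDC20, an activator of the anaphase-promoting complex, fell from 85.4 ± 5.12 to 39.1 ± 1.27 CPM (−1.13 ± 0.07, adjusted p = 5.92e-11), and PLK1, a mitotic kinase, fell as well (−1.01 ± 0.08, adjusted p = 3.34e-09).

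**Figure D1:**
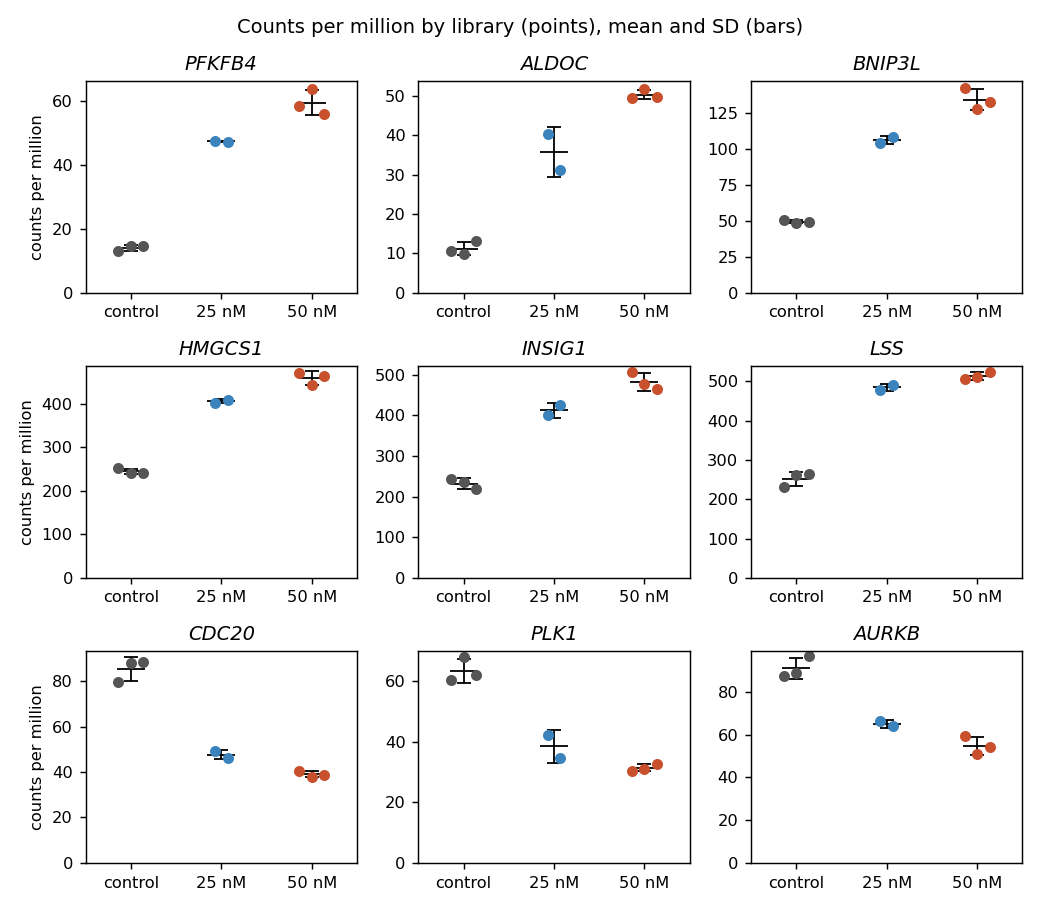
CPM with TMM scaling (vertical axis, starting at 0) of 9 genes in each of the 8 libraries (points), by dose of TSN, with the mean and SD of each group as bars. PFKFB4, ALDOC, BNIP3L, HMGCS1, INSIG1 and LSS were higher at both doses than in control, while CDC20, PLK1 and AURKB were lower. CDC20 had means of 85.4, 47.7 and 39.1 CPM at 0, 25 and 50 nM.

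Of 13064 genes tested at 50 nM, 1902 were called higher and 2197 lower, so 46.4% of the called genes were higher. Total-count scaling gave 2134 higher and 1932 lower genes (52.5% higher), and the length and GC correction 1592 and 2577 (38.2% higher), so which direction held more genes depended on the processing. Most changes were small: 145 genes rose and 23 fell by more than 2-fold, or 79 and 15 with DESeq2 and 42 and 6 with only genes of at least 5 CPM. Among protein-coding genes with a mean of at least 5 CPM and every 50 nM library on the same side of every control library, the largest rise was that of RGS1, a brake on G protein signalling in B cells (2.36 ± 0.16, 2.53 to 13.1 CPM, adjusted p = 4.29e-10). ALDOC and PFKFB4 followed, and then PSD3 (1.83 ± 0.07), SCIMP, an adaptor at the B-cell membrane (1.78 ± 0.10), ST3GAL5, which makes the ganglioside GM3 (1.69 ± 0.14), RENBP (1.68 ± 0.18) and BNIP3L, a mitophagy receptor (1.44 ± 0.06). Among the most abundant genes that rose by more than 2-fold were LSS, the lanosterol synthase (1.03 ± 0.06, 252 to 514 CPM), INSIG1 and CLCN6, a chloride and proton exchanger of late endosomes (1.07 ± 0.07). The falls beyond 2-fold that met the same rule were those of CDC20, PLK1, PIF1, a DNA helicase (−1.09 ± 0.10), GPX1, a glutathione peroxidase (−1.03 ± 0.07), the mitochondrial ribosomal gene MRPS28 (−1.10 ± 0.13), BOLA2B (−4.79 ± 1.09, adjusted p = 0.00172) and BOLA2 (−3.85 ± 0.90, adjusted p = 0.00227). The fall of BOLA2 and BOLA2B, near-identical copies whose reads cannot be assigned with certainty, rested on control replicate 3. Without that library their changes were −0.73 (adjusted p = 0.168) and −1.13 (adjusted p = 0.102).

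Sterol genes formed the list with the smallest p. Of 25 measured genes of cholesterol synthesis and uptake, targets of the transcription factor SREBP2, 24 were called higher and 1 lower, with the same counts when adjusted over the list alone. The list had a median of 0.73 (camera, adjusted p = 5.18e-48, and adjusted p = 0.000458 with an estimated correlation). HMGCS1 (0.91 ± 0.05), which feeds the mevalonate pathway, rose together with LSS and INSIG1. PMVK fell (−0.37, named after its value was seen). Fatty acid synthesis genes, regulated mainly by SREBP1, had 9 of 12 members higher and 1 lower, by either adjustment, with a median of 0.29 (adjusted p = 8.39e-08). LPIN1 (0.83 ± 0.05), SCD (0.72 ± 0.05) and ACSS2 (1.11 ± 0.15) were among the rises, and SREBF1, the gene of SREBP1 itself, fell (−0.17, named after its value was seen).

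Hypoxia and glycolysis genes had 16 of 23 members higher and 0 lower (17 and 0 adjusted over the list alone). Their median was 0.38 (adjusted p = 1.47e-26, and adjusted p = 0.0101 with an estimated correlation). Besides ALDOC, PFKFB4 and BNIP3L, PDK1, a kinase that keeps pyruvate out of the citric acid cycle, rose 2.17-fold (1.12 ± 0.06). FOXO target genes had 9 of 16 members higher and 1 lower by either adjustment (median 0.37, adjusted p = 8.68e-06). SESN3 (0.77 ± 0.07), TXNIP (0.63 ± 0.06), which limits glucose uptake, and IL7R (0.67 ± 0.07) rose, and GADD45A fell (−0.58, named after its value was seen). Lysosome and autophagy genes regulated by TFEB had 12 of 30 members higher and 1 lower by either adjustment, with a median of 0.10 and a mean of 0.24 (adjusted p = 0.000316). FNIP1 (0.86 ± 0.08), RRAGD (0.97 ± 0.10) and FLCN (0.66 ± 0.08), which act in nutrient signalling to mTORC1, and MAP1LC3B (0.52 ± 0.06), of the autophagosome, were the rises with the smallest p. TFEB itself fell (−0.37, named after its value was seen).

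Proliferation genes moved down. In the list of mitosis and G2/M genes, 0 of 30 were higher and 27 were lower by either adjustment. Their median was −0.46 (adjusted p = 3.1e-24, and adjusted p = 0.0294 with an estimated correlation). UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex (−0.84 ± 0.07), and AURKB, a kinase of chromosome segregation (−0.73 ± 0.07), fell with CDC20 and PLK1, and MKI67, the gene of the proliferation antigen Ki-67, fell (−0.33 ± 0.06, adjusted p = 0.000104). DNA replication and G1/S genes had 1 of 35 members higher and 24 lower (1 and 27 adjusted over the list alone), with a median of −0.24 (adjusted p = 1.49e-09). The replicative helicase subunit MCM7 (−0.51 ± 0.06), CDT1, which loads that helicase (−0.43 ± 0.06), and the transcription factor E2F1 (−0.40 ± 0.05) fell, and CCNE2 rose (0.27, named after its value was seen). Ribosome biogenesis genes and MYC targets had 0 of 26 higher and 21 lower (0 and 23 adjusted over the list alone; median −0.31, adjusted p = 1.44e-12). FBL (−0.50 ± 0.06), BOP1 (−0.49 ± 0.06) and SRM (−0.57 ± 0.07) were examples, and MYC fell as well (−0.24 ± 0.06, adjusted p = 0.00216). DNA repair genes had 2 of 24 higher and 6 lower (2 and 8 adjusted over the list alone), and the list was not called (median −0.09, adjusted p = 0.233). In it ATM, the double-strand break kinase, rose (0.60 ± 0.06), MRE11 rose (0.21, named after its value was seen) and the checkpoint kinase gene CHEK1 fell (−0.34 ± 0.07). After removal of a length and GC trend, an alternative chosen after seeing the data, the DNA repair list was called lower (median −0.17, adjusted p = 0.000513).

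Genes of protein turnover, protein folding and respiration were also lower. Proteasome subunits had 0 of 27 higher and 20 lower (0 and 22 adjusted over the list alone; median −0.27, adjusted p = 3.82e-09), among them PSMC3 (−0.47 ± 0.06) and PSMA7 (−0.47 ± 0.06). The list of nuclear-encoded oxidative phosphorylation had 1 of 30 members higher and 18 lower (2 and 20 adjusted over the list alone), with a median of −0.20 (adjusted p = 5.14e-06). CYC1, the cytochrome c1 gene, fell (−0.65 ± 0.07), as did the complex I gene NDUFV1 (−0.39 ± 0.06), whereas SDHA rose (0.17, named after its value was seen). Endoplasmic reticulum chaperones and XBP1/ATF6 targets had 1 of 24 higher and 13 lower (3 and 14 adjusted over the list alone; median −0.22, adjusted p = 1.32e-05, but adjusted p = 0.0551 with an estimated correlation). SDF2L1 (−0.98 ± 0.08), HYOU1 (−0.54 ± 0.06) and CALR (−0.44 ± 0.05) fell, and EDEM1 rose (0.23, named after its value was seen). HSF1 heat shock genes had 0 of 17 higher and 10 lower by either adjustment (median −0.19, adjusted p = 0.00099, and adjusted p = 0.0507 with an estimated correlation), FKBP4 (−0.51 ± 0.05) and STIP1 (−0.43 ± 0.06) among them. ATF4 target genes had 2 of 29 higher and 15 lower (2 and 16 adjusted over the list alone; median −0.17, adjusted p = 0.000843). The amino acid transporter gene SLC7A5 (−0.48 ± 0.05) and PHGDH, of serine synthesis (−0.44 ± 0.05), fell, while DDIT4, an inhibitor of mTORC1 signalling that is also induced by hypoxia (0.85 ± 0.06), and the amino acid transporter gene SLC38A2 (0.56 ± 0.07) rose.

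Among B-cell genes, called rises outnumbered called falls in the germinal centre, B cell receptor, class II and NF-kappaB lists but not in the plasma cell and class I lists. Germinal centre B cell markers had 10 of 22 higher and 1 lower by either adjustment (median 0.15, adjusted p = 1.43e-05). KLHL6 (0.77 ± 0.05), RGS13 (0.76 ± 0.06) and IRAG2 (0.48 ± 0.05) rose, EZH2 fell (−0.16, named after its value was seen), and BCL6 changed by 0.02 ± 0.06 (adjusted p = 0.842). B cell receptor signalling and B cell surface genes had 12 of 23 higher and 1 lower (12 and 2 adjusted over the list alone; median 0.16, adjusted p = 0.000771, but adjusted p = 0.191 with an estimated correlation). The inhibitory co-receptor gene CD72 (1.15 ± 0.07), CXCR5, the receptor that guides B cells into follicles (0.75 ± 0.10), and MS4A1, which encodes CD20 (0.35 ± 0.05), rose, and VPREB3 fell (−0.56 ± 0.06). MHC class II antigen presentation genes had 7 of 12 higher and 1 lower by either adjustment (median 0.22, adjusted p = 9.36e-05, but adjusted p = 0.191 with an estimated correlation), among them HLA-DMA (0.57 ± 0.06), HLA-DMB (0.53 ± 0.06) and the transactivator gene CIITA (0.44 ± 0.06). CD74 fell (−0.17, named after its value was seen). NF-kappaB target genes had 7 of 15 higher and 0 lower (9 and 0 adjusted over the list alone; median 0.31, adjusted p = 0.000771), with CD83 (0.84 ± 0.06), NFKB2 (0.45 ± 0.08) and REL (0.39 ± 0.06) as examples. Plasma cell and activated B cell markers had 2 of 11 higher and 4 lower (2 and 5 adjusted over the list alone, median −0.23, adjusted p = 0.174), the falls including XBP1 (−0.40 ± 0.06) and TNFRSF17 (−0.49 ± 0.10). Camera did not call the plasma cell list, but fry called it lower (adjusted p = 0.00125). MHC class I antigen presentation genes had 2 of 15 higher and 5 lower by either adjustment (median −0.06, adjusted p = 0.365); HLA-E rose (0.32 ± 0.05) and PSMB8 of the immunoproteasome fell (−0.36 ± 0.06).

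Immediate early and AP-1 genes had 8 of 21 higher and 2 lower by either adjustment (median 0.30, adjusted p = 0.00524, but adjusted p = 0.0504 with an estimated correlation). NR4A3 (2.19 ± 0.25), EGR2 (1.94 ± 0.24) and EGR1 (1.96 ± 0.25) rose. Their control means lay between 1.12 and 1.51 CPM, so few reads supported them, and with only genes of at least 5 CPM the immediate early and AP-1 list was not called (adjusted p = 0.311). Interferon-stimulated genes had 6 of 20 higher and 2 lower (7 and 2 adjusted over the list alone; median 0.47, adjusted p = 0.01, but adjusted p = 0.207 with an estimated correlation). STAT2 (0.75 ± 0.06) and OAS1 (1.00 ± 0.14) rose and BST2 fell (−0.27 ± 0.05); with only genes of at least 5 CPM this list was not called either (median 0.12, adjusted p = 0.127). The mitochondrial share of counts was 4.03% ± 0.333 in control (SD, n = 3) and 5.11% ± 0.258 at 50 nM, with every 50 nM library above every control library (exact permutation test, two-sided, p = 0.1, the smallest this design allows). Mitochondrially encoded mRNAs had 8 of 13 higher and 0 lower by either adjustment, COX1 (0.42 ± 0.10) and ND4 (0.35 ± 0.10) among them (median 0.26, adjusted p = 0.029, but adjusted p = 0.603 with an estimated correlation). Without control replicate 2 the adjusted p of mitochondrially encoded mRNAs was 0.171, without 50 nM replicate 3 it was 0.0582, and with only genes of at least 5 CPM it was 0.0558.

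Cell death and stress lists were mixed at 50 nM. The p53 target genes had 5 of 23 higher and 7 lower by either adjustment (median −0.06, adjusted p = 0.445). TP53INP1 rose (0.75 ± 0.09), AEN (−0.48 ± 0.05) and BAX (−0.45 ± 0.07) fell, and CDKN1A, the p21 gene, changed by 0.11 ± 0.06 (adjusted p = 0.125). After the length and GC correction CDKN1A was called, at 0.19 (adjusted p = 0.00415). The pro-apoptotic BCL2 family had 2 of 10 higher, HRK (0.69 ± 0.06) and BCL2L11 (0.29 ± 0.07), and 3 lower, BAX, BID (−0.48 ± 0.08) and BAK1 (−0.41, named after its value was seen), or 3 and 4 adjusted over the list alone. Its median was −0.06 and its mean −0.01, while the test pointed upwards (adjusted p = 0.964). In the pro-survival BCL2 family 1 of 5 was higher by either adjustment, BCL2A1 (0.88 ± 0.23), with a median of −0.04 and a mean of 0.15 (adjusted p = 0.682). BCL2 itself changed by 0.13 ± 0.05 (adjusted p = 0.0701) and MCL1 by −0.05 ± 0.06 (adjusted p = 0.516). BCL2 was called with total-count scaling (adjusted p = 0.0334), with only genes of at least 5 CPM (adjusted p = 0.0381) and with the replicate number as a block (adjusted p = 0.045). MCL1 was called lower after the length and GC correction (−0.14, adjusted p = 0.0293). NRF2 target genes had 1 of 15 higher and 4 lower by either adjustment (median −0.10, adjusted p = 0.174), the falls being TXN (−0.34), TXNRD1 (−0.26), TALDO1 (−0.24) and SRXN1 (−0.70). Camera did not call the NRF2 list, but fry called it lower (adjusted p = 0.000179). The call of SRXN1 was lost without control replicate 2 or 3 (adjusted p = 0.064 and 0.0514) or without 50 nM replicate 1 or 3 (adjusted p = 0.0711 and 0.0699). Without a filter on low counts the lists of NRF2 target genes and DNA repair were called lower (adjusted p = 0.0403 and 0.0273), as was that of cytosolic ribosomal proteins (adjusted p = 0.0367). In the filtered fit, cytosolic ribosomal proteins, a family with many pseudogene copies, had 3 of 46 higher and 8 lower (3 and 6 adjusted over the list alone; median −0.04, adjusted p = 0.271). Markers of other cell types were few: 7 T and NK cell markers were measured, with 1 higher and 2 lower (median −0.30, adjusted p = 0.815). Of 2 myeloid cell markers 1 was higher (1 and 1 adjusted over the list alone; adjusted p = 0.618), and of 3 epithelial and stromal cell markers 1 was lower (adjusted p = 0.682).

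**Figure D2:**
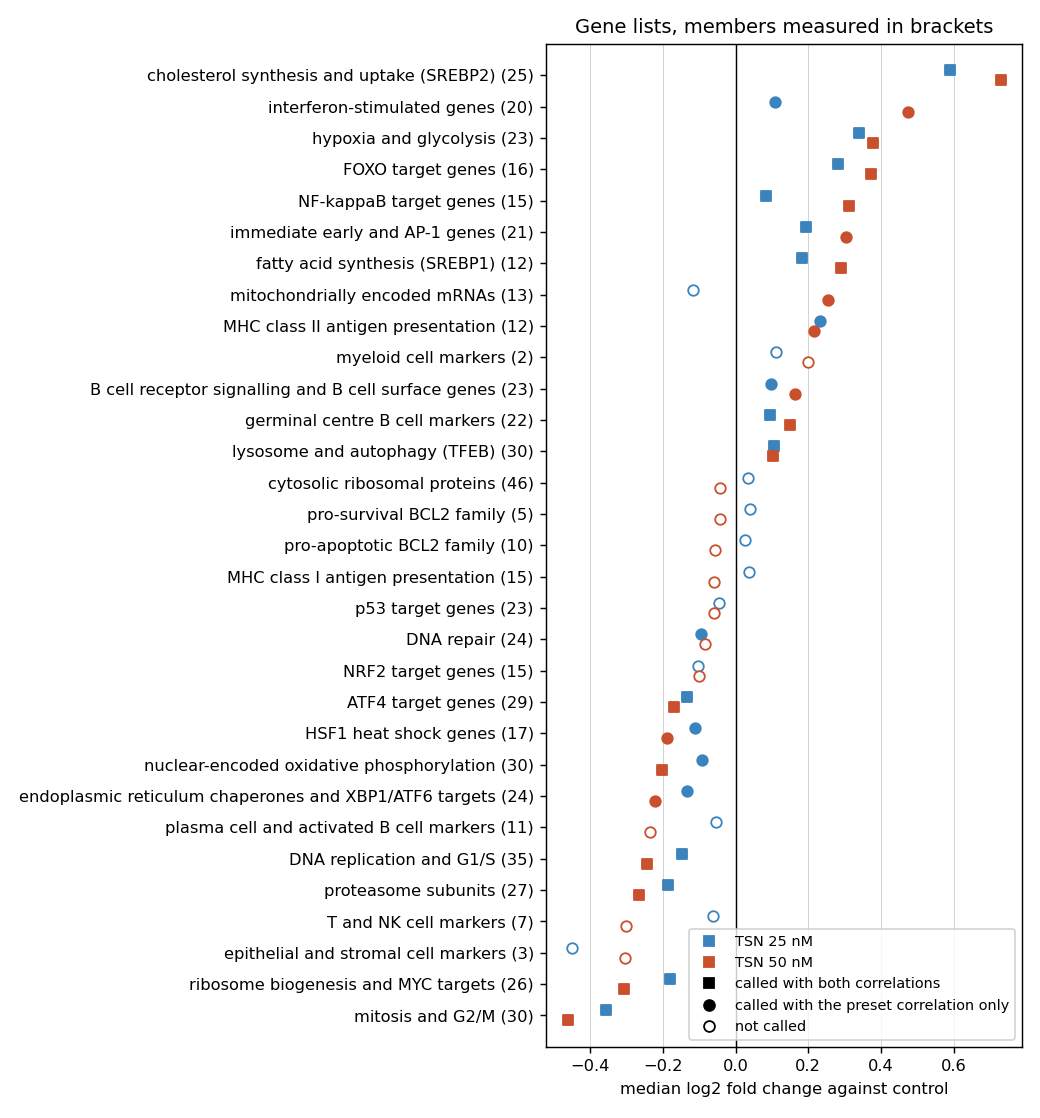
Median log2 fold change against control (horizontal axis) of the measured members of 31 gene lists (vertical axis, number measured in brackets) at 25 nM and 50 nM TSN. Squares mark lists called by camera with the preset and with the estimated correlation, filled circles those called with the preset correlation alone, and open circles those not called. Cholesterol synthesis and uptake lay highest at both doses (0.59 and 0.73), and mitosis and G2/M lay lowest at 50 nM (−0.46).

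Camera called 20 of the 31 lists at 50 nM with the preset correlation, 12 higher and 8 lower, and 13 of them with an estimated correlation. With the estimated correlation the adjusted p of those 13 lists ran from 0.000458 (cholesterol synthesis and uptake) to 0.0372 (FOXO target genes). The far smaller values given above rest on the preset correlation. Changes also followed transcript length: the median at 50 nM was −0.21 for the 498 genes under 1000 nt, where 43.8% were lower, and 0.08 for the 3615 genes over 4000 nt, where 26.7% were higher. The proteasome, ribosome biogenesis, oxidative phosphorylation, sterol and hypoxia lists were called in the same direction after that trend was removed. Reads of CD72, CXCR5, FADS2, NEIL1, TP53INP1, CIITA, TXNRD1, PSMB8, MCM7, BOP1, ATM, SH3D21 and the HLA genes are less certain, since these genes overlap others or have close relatives and the strand of counting is not given in the sources used here.

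The second comparison set 25 nM TSN (n = 2 libraries) against the same 3 control libraries. The same kinds of genes stood at its top. PFKFB4 rose 3.38-fold (1.76 ± 0.09, adjusted p = 2.32e-11), ALDOC 3.19-fold (1.68 ± 0.12, adjusted p = 2.38e-09) and BNIP3L 2.15-fold (1.10 ± 0.07, adjusted p = 3.71e-10). LSS (0.94 ± 0.06) and INSIG1 (0.83 ± 0.06) rose by slightly less than 2-fold. CDC20 fell from 85.4 ± 5.12 to 47.7 ± 2.07 CPM (−0.84 ± 0.07, adjusted p = 1.13e-07), and PLK1 fell by 0.72 on the log2 scale (adjusted p = 9.59e-06).

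At this dose 538 genes were called higher and 428 lower, 36 and 7 of them by more than 2-fold. Over 2-fold there were 19 and 1 genes with DESeq2, 18 and 1 with only genes of at least 5 CPM, and 48 and 13 without a filter on low counts. Besides the genes above, the rule selected RENBP (1.56 ± 0.20), RGS1 (1.44 ± 0.19), ST3GAL5 (1.38 ± 0.15), PSD3 (1.33 ± 0.08), SH3D21 (1.24 ± 0.16), SCIMP (1.16 ± 0.11) and the adhesion receptor gene NECTIN1 (1.11 ± 0.07) among the rises. Only HMCN1, an extracellular matrix gene, met it among the falls (SE 0.20, adjusted p = 0.00288), and without 25 nM replicate 2 HMCN1 was not called (−0.71, adjusted p = 0.0739). BOLA2 and BOLA2B were called lower here as well, but not without control replicate 3 (adjusted p = 0.807 and 0.768), 25 nM replicate 1 (adjusted p = 0.165 and 0.154) or 25 nM replicate 2 (adjusted p = 0.0993 and 0.086).

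In the cholesterol synthesis and uptake list 23 of 25 genes rose and 0 fell by either adjustment. The median was 0.59 (adjusted p = 1.72e-70, and adjusted p = 0.000175 with an estimated correlation). For hypoxia and glycolysis the counts were 16 higher and 0 lower of 23 (19 and 0 adjusted over the list alone). Its median was 0.34 (adjusted p = 5.23e-42, and adjusted p = 0.00327 with an estimated correlation). Mitosis and G2/M genes had 0 higher and 23 lower of 30 (0 and 26 adjusted over the list alone), UBE2C (−0.49 ± 0.08), AURKB (−0.48 ± 0.07) and MKI67 (−0.37 ± 0.06) among them. Their median was −0.36 (adjusted p = 8.94e-29, and adjusted p = 0.0342 with an estimated correlation). In other lists fewer members were lower and none was called higher. This held for ribosome biogenesis and MYC targets (8 of 26 lower, 19 adjusted over the list alone; median −0.18, adjusted p = 1.45e-10) and for proteasome subunits (7 of 27 lower, 15 adjusted over the list alone; median −0.19, adjusted p = 8.58e-07). It also held for DNA replication and G1/S (6 of 35 lower, 16 adjusted over the list alone; median −0.15, adjusted p = 4.42e-06). SRM (−0.41 ± 0.08), PSMB2 (−0.28 ± 0.06) and MCM7 (−0.28 ± 0.06) were examples, though MCM7 was not called without 25 nM replicate 2 (adjusted p = 0.0771). Fatty acid synthesis genes had 4 of 12 higher, namely LPIN1 (0.57 ± 0.06), SCD (0.47 ± 0.06), ACSS2 (0.80 ± 0.17) and FADS2 (0.38 ± 0.06), or 7 adjusted over the list alone, and 0 lower (median 0.18, adjusted p = 6.71e-07). FOXO target genes had 8 of 16 higher and 0 lower (8 and 1 adjusted over the list alone; median 0.28, adjusted p = 4.42e-06), with TXNIP (0.59 ± 0.06) and SESN3 (0.46 ± 0.07) as examples.

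Germinal centre B cell markers had 5 of 22 higher, KLHL6 (0.59 ± 0.06), NEIL1 (0.62 ± 0.07), RGS13 (0.45 ± 0.07), IRAG2 (0.24 ± 0.06) and ITPKB (0.38, named after its value was seen), and 7 adjusted over the list alone (median 0.10, adjusted p = 5.72e-05). IRAG2 was not called without control replicate 2 (adjusted p = 0.0554). NF-kappaB target genes had 4 of 15 higher (6 adjusted over the list alone; median 0.09, mean 0.18, adjusted p = 0.000581), CD83 (0.63 ± 0.07) and NFKB2 (0.48 ± 0.08) with the smallest p, besides RELB (0.28) and CD40 (0.40), named after their values were seen. Lysosome and autophagy genes had 7 of 30 higher (8 adjusted over the list alone; median 0.11, adjusted p = 0.000297), among them RRAGD (0.65 ± 0.12) and FLCN (0.56 ± 0.09). Immediate early and AP-1 genes had 2 of 21 higher, NR4A3 (1.66 ± 0.28) and EGR2 (1.28 ± 0.28), or 4 adjusted over the list alone (median 0.19, adjusted p = 0.000979, and adjusted p = 0.115 with only genes of at least 5 CPM). ATF4 target genes had 2 of 29 higher, DDIT4 (0.79 ± 0.07) and SLC38A2 (0.29 ± 0.08), and 5 lower (2 and 9 adjusted over the list alone; median −0.13, adjusted p = 0.00431), SLC7A5 (−0.42 ± 0.06) having the smallest p. The others were PHGDH (−0.20 ± 0.06) and, named after their values were seen, SLC1A5, SHMT2 and GARS1. Without 25 nM replicate 2 SLC38A2 was not called (adjusted p = 0.372), nor without control replicate 2 (adjusted p = 0.128) or 3 (adjusted p = 0.0916). PHGDH was not called without control replicate 2 (adjusted p = 0.18) or 3 (adjusted p = 0.119), without either 25 nM library (adjusted p = 0.123 and 0.121) or without 50 nM replicate 2 (adjusted p = 0.0712) or 3 (adjusted p = 0.0544).

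Another 7 lists were called by camera at 25 nM with the preset correlation but not with an estimated one. Fry called all 7 in the same direction (adjusted p = 0.00841 to 0.0413). Endoplasmic reticulum chaperones and XBP1/ATF6 targets had 0 of 24 higher and 7 lower (0 and 11 adjusted over the list alone; median −0.13, adjusted p = 0.000215, adjusted p = 0.1 with an estimated correlation). HSF1 heat shock genes had 0 of 17 higher and 2 lower, STIP1 and FKBP4 (0 and 3 adjusted over the list alone; median −0.11, adjusted p = 0.00144, adjusted p = 0.0615 with an estimated correlation). DNA repair genes had 1 of 24 higher, ATM, and 3 lower, CHEK1, BRCA2 and RAD51C (1 and 5 adjusted over the list alone; median −0.10, adjusted p = 0.00641, adjusted p = 0.295 with an estimated correlation). BRCA2 and RAD51C are named after their values were seen. In the list of nuclear-encoded oxidative phosphorylation 1 of 30 was higher, SDHA, and 1 lower, CYC1, by either adjustment (median −0.09, adjusted p = 0.00945, adjusted p = 0.122 with an estimated correlation). B cell receptor signalling and B cell surface genes had 6 of 23 higher and 1 lower, VPREB3 (7 and 1 adjusted over the list alone; median 0.10, adjusted p = 0.00147, adjusted p = 0.205 with an estimated correlation). MHC class II antigen presentation genes had 5 of 12 higher, including HLA-DMB (0.49 ± 0.06) and HLA-DMA (0.40 ± 0.07), and 0 lower (7 and 1 adjusted over the list alone; median 0.23, adjusted p = 1.44e-05, adjusted p = 0.144 with an estimated correlation). Interferon-stimulated genes had 2 of 20 higher, STAT2 (0.60 ± 0.06) and OAS1 (0.82 ± 0.15), and 0 lower (3 and 0 adjusted over the list alone; median 0.11, adjusted p = 0.0213, adjusted p = 0.25 with an estimated correlation). Without 25 nM replicate 1 the lists of DNA repair (adjusted p = 0.277), B cell receptor signalling and B cell surface genes (adjusted p = 0.0685) and interferon-stimulated genes (adjusted p = 0.111) were not called. Interferon-stimulated genes were called neither without control replicate 2 (adjusted p = 0.0903) nor without a filter on low counts (adjusted p = 0.103). Among the genes named here, CHEK1 (adjusted p = 0.0558), OAS1 (adjusted p = 0.0561) and CYC1 (adjusted p = 0.071) were not called without 25 nM replicate 1. STIP1 (adjusted p = 0.0508), ATM (adjusted p = 0.0585) and VPREB3 (adjusted p = 0.102) were not called without 25 nM replicate 2. CYC1 was also not called without control replicate 2 (adjusted p = 0.0559).

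The p53 target genes were not called at 25 nM (2 higher and 2 lower of 23, median −0.04, adjusted p = 0.415). Nor were the pro-survival (0 and 0 of 5, adjusted p = 0.719) and pro-apoptotic (1 and 2 of 10, adjusted p = 0.766) BCL2 families. The same held for NRF2 target genes (0 and 1 of 15, adjusted p = 0.11) and for plasma cell and activated B cell markers (0 and 1 of 11, or 0 and 4 adjusted over the list alone, adjusted p = 0.219). Fry, however, called NRF2 target genes (adjusted p = 0.00151) and the plasma cell list (adjusted p = 0.0199) lower. Another list that camera did not call was that of cytosolic ribosomal proteins (0 and 0 of 46, median 0.04, adjusted p = 0.243). MHC class I antigen presentation genes had 2 higher and 1 lower of 15, with a median of 0.04, a mean near 0 and the opposite sign (−0.003), and a test pointing upwards (adjusted p = 0.792). Apart from the plasma cell list, the counts of these lists were the same when adjusted over the list alone. The markers of T and NK cells (1 and 0 of 7, adjusted p = 0.941), myeloid cells (0 and 0 of 2, adjusted p = 0.734) and epithelial and stromal cells (0 and 0 of 3, adjusted p = 0.209) were not called. Mitochondrially encoded mRNAs had 0 of 13 called in either direction, by either adjustment (median −0.12, adjusted p = 0.198, and adjusted p = 0.754 with an estimated correlation). The mitochondrial share differed between the 25 nM libraries, 4.79% in replicate 1 and 3.08% in replicate 2 (exact permutation test against control, two-sided, p = 0.9). With 1 library left at 25 nM, the median of the mitochondrially encoded mRNAs was −0.43 without replicate 1 and 0.17 without replicate 2. Its sign thus followed the library left out. Without control replicate 2 these mRNAs were called lower with the preset correlation (median −0.17, adjusted p = 0.0128). MYC fell by 0.25 on the log2 scale (adjusted p = 0.019), a call lost without control replicate 2 (adjusted p = 0.0681), control replicate 3 (adjusted p = 0.0723) or 25 nM replicate 2 (adjusted p = 0.207).

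The gene counts at 25 nM changed when 1 library was left out. Without control replicate 2 there were 344 higher and 168 lower genes, and without control replicate 3 428 and 252. Without control replicate 1 there were 432 and 325, but without 50 nM replicate 1 604 and 544. A loss of power with fewer libraries was not told apart from dependence on a given library. The share of called genes that were higher was 55.7%, and 39.3% (651 higher, 1005 lower) after the length and GC correction.

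The third comparison tested 50 nM directly against 25 nM. RGS1 was higher at 50 nM, by 1.9-fold (0.92 ± 0.16, adjusted p = 0.00468), as was SCIMP (0.62 ± 0.10, adjusted p = 0.00374). TIMM10, of mitochondrial protein import (−0.60 ± 0.09, adjusted p = 0.00194), the chaperone cofactor gene SDF2L1 (−0.59 ± 0.09, adjusted p = 0.00194), MRPS28 (−0.72 ± 0.14, adjusted p = 0.0101) and TMEM238 (−0.71 ± 0.13, adjusted p = 0.00559) were lower. The rule also selected DMD (0.57 ± 0.14), the mitochondrially encoded CYTB (0.53 ± 0.13) and HIVEP1 (0.51 ± 0.11) among the rises, and GRIN3B (−0.70 ± 0.15) among the falls. Reads of GRIN3B cannot be told apart with certainty from those of the far more abundant TMEM259, which it overlaps. Without 25 nM replicate 2, CYTB (adjusted p = 0.204), HIVEP1 (adjusted p = 0.0889), DMD (adjusted p = 0.0799) and MRPS28 (adjusted p = 0.0709) were not called. DMD was also lost without 25 nM replicate 1 (adjusted p = 0.147) or any 50 nM library (adjusted p = 0.0551 to 0.0711). CYTB was lost without 50 nM replicate 2 (adjusted p = 0.0813) or 3 (adjusted p = 0.0561), and GRIN3B was lost without 25 nM replicate 1 (adjusted p = 0.0805) or 50 nM replicate 2 (adjusted p = 0.0601). After the length and GC correction TMEM238 (adjusted p = 0.0691), HIVEP1 (adjusted p = 0.0528), GRIN3B (adjusted p = 0.0616) and DMD (adjusted p = 0.112) were not called.

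In all, 156 genes were called higher and 377 lower at 50 nM than at 25 nM, 5 and 4 of them by more than 2-fold. The latter, named after their values were seen, were CD69, RORA, ZFP14 and the pseudogenes PPIP5K1P1 and RPL23AP42 on the higher side and MAGED4B, SNORD100, RPS2P55 and LOC644669 on the lower side. The counts over 2-fold were small and moved with the processing. DESeq2 gave 0 and 0 (215 higher and 489 lower genes of any size), with 6079 genes left without an adjusted p. Over 2-fold the counts were 1 and 1 with only genes of at least 5 CPM, and 13 and 12 without a filter on low counts. With a library left out they ran from 3 higher (without 25 nM replicate 2 or 50 nM replicate 2) to 11 higher (without 25 nM replicate 1), and from 1 lower (without 50 nM replicate 2) to 9 lower (without 50 nM replicate 1). The counts of any size, 156 higher and 377 lower, fell to 29 and 93 without 50 nM replicate 2, 47 and 120 without 25 nM replicate 2, 86 and 225 without control replicate 2, 91 and 262 without 50 nM replicate 1, and 103 and 299 without 50 nM replicate 3. Camera called 14 lists with the preset correlation and 0 with an estimated one, where 7 lists had an unadjusted value under 0.05, while fry called 12.

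At the higher dose, DNA replication and G1/S genes stood lower (7 of 35 lower, 10 adjusted over the list alone; median −0.14, adjusted p = 5.01e-06, adjusted p = 0.106 with an estimated correlation). The list of nuclear-encoded oxidative phosphorylation stood lower too (8 of 30, or 1 higher and 14 lower adjusted over the list alone; median −0.13, adjusted p = 5.01e-06, adjusted p = 0.079 with an estimated correlation). E2F1 (−0.27 ± 0.06) and CYC1 (−0.34 ± 0.07) were examples. Ribosome biogenesis and MYC targets (4 of 26 lower, 7 adjusted over the list alone; median −0.14, adjusted p = 2.42e-05, adjusted p = 0.139 with an estimated correlation) were lower too. So were mitosis and G2/M genes (4 of 30 lower, 8 adjusted over the list alone; median −0.15, adjusted p = 5.85e-05, adjusted p = 0.235 with an estimated correlation) and proteasome subunits (3 of 27 lower, 5 adjusted over the list alone; median −0.11, adjusted p = 5.85e-05, adjusted p = 0.079 with an estimated correlation). CDC20 (−0.29 ± 0.08), UBE2C (−0.34 ± 0.08), FBL (−0.28 ± 0.07) and PSMA7 (−0.27 ± 0.07) passed the test. Endoplasmic reticulum chaperones and XBP1/ATF6 targets (3 of 24 lower, 4 adjusted over the list alone; median −0.09, adjusted p = 0.00405, adjusted p = 0.235 with an estimated correlation) were lower at 50 nM. So were ATF4 target genes (2 of 29 lower, 1 higher and 2 lower adjusted over the list alone; median −0.08, adjusted p = 0.0386, adjusted p = 0.185 with an estimated correlation). The last list on the lower side was that of cytosolic ribosomal proteins (2 of 46 higher and 6 lower, 2 and 9 adjusted over the list alone; median −0.09, adjusted p = 0.000889, adjusted p = 0.221 with an estimated correlation).

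Cholesterol synthesis and uptake genes stood higher at 50 nM than at 25 nM (4 of 25 higher and 1 lower, 9 and 1 adjusted over the list alone; median 0.15, adjusted p = 3.2e-05, adjusted p = 0.079 with an estimated correlation), INSIG1 (0.23 ± 0.06) among them. So did fatty acid synthesis genes (2 of 12 higher, SCD and LPIN1, or 5 and 1 lower adjusted over the list alone; median 0.15, adjusted p = 0.00218, adjusted p = 0.221 with an estimated correlation). Hypoxia and glycolysis genes were higher as well (4 of 23 higher, PFKFB4, ALDOC, PDK1 and BNIP3L, or 4 and 1 lower adjusted over the list alone; median 0.05, adjusted p = 0.0106, adjusted p = 0.235 with an estimated correlation). Another higher list was that of germinal centre B cell markers (2 of 22 higher, RGS13 and IRAG2, 4 adjusted over the list alone; median 0.06, adjusted p = 0.0132, adjusted p = 0.185 with an estimated correlation). FOXO target genes were called higher (1 of 16 higher, SESN3, or 3 and 1 lower adjusted over the list alone; median 0.08, adjusted p = 0.044, adjusted p = 0.235 with an estimated correlation). Mitochondrially encoded mRNAs were higher too (4 of 13 higher, 9 adjusted over the list alone; median 0.32, adjusted p = 4.04e-07, adjusted p = 0.235 with an estimated correlation). Without 25 nM replicate 2, mitochondrially encoded mRNAs (adjusted p = 0.353), hypoxia and glycolysis (adjusted p = 0.115), fatty acid synthesis (SREBP1) (adjusted p = 0.115), germinal centre B cell markers (adjusted p = 0.235) and endoplasmic reticulum chaperones and XBP1/ATF6 targets (adjusted p = 0.127) were not called. Without 25 nM replicate 1 cytosolic ribosomal proteins were not (adjusted p = 0.112). The calls of ATF4 target genes and FOXO target genes each ended without 25 nM replicate 1 (adjusted p = 0.113 and 0.276), without 50 nM replicate 1 (0.0567 and 0.0694) and without 50 nM replicate 2 (0.0521 in both). That of ATF4 target genes also ended without 25 nM replicate 2 (adjusted p = 0.0563). With only genes of at least 5 CPM the call of ATF4 target genes ended (adjusted p = 0.052), and with only the libraries of the groups compared that of FOXO target genes ended (adjusted p = 0.0778).

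Transcript length bore on these list calls between doses. After the length and GC correction 18 of 31 lists kept their result, while the calls of ATF4 target genes (adjusted p = 0.123) and FOXO target genes (adjusted p = 0.234) ended and 7 lists were newly called. HSF1 heat shock genes were then lower (median −0.07, adjusted p = 0.00951). Newly higher were B cell receptor signalling and B cell surface genes (adjusted p = 0.000121), MHC class II antigen presentation (adjusted p = 0.00221), lysosome and autophagy (TFEB) (adjusted p = 0.0107) and NF-kappaB target genes (adjusted p = 0.0122). Immediate early and AP-1 genes (adjusted p = 0.0122) and interferon-stimulated genes (adjusted p = 0.0191) were newly higher too. Without that correction, B cell receptor signalling and B cell surface genes (adjusted p = 0.0642 with every library) were called without control replicate 1 (adjusted p = 0.0378), 25 nM replicate 1 (adjusted p = 0.0039) or 50 nM replicate 1 (adjusted p = 0.00863). HSF1 heat shock genes (adjusted p = 0.0942 with every library) were called without 50 nM replicate 1 (adjusted p = 0.0261), as was lysosome and autophagy (TFEB) (adjusted p = 0.0454). MHC class II antigen presentation was called without 25 nM replicate 1 (adjusted p = 0.037).

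The changes at both doses against control were then set side by side. Of the 966 genes called at 25 nM, 962 had the same direction at 50 nM, and 755 (78.2%) changed more there, with a median size of 0.46 at 50 nM and 0.33 at 25 nM. Called at both doses were 511 genes with a rise, PFKFB4, ALDOC, INSIG1 and LSS among them, and 405 with a fall, CDC20 and PLK1 among them; 0 genes were called in opposite directions. Independent lists of these sizes would share 78.3 and 72.0 genes, and in 50 simulations of unchanged groups against the shared controls 0.16 and 0.08 genes were shared on average. Almost no genes were called in those simulations, so their overlap was bound to be near 0. It does not show what shared controls give when many genes are called. Opposite calls numbered 0 in the simulations too, so their absence here is no evidence of agreement. Over all genes 76.5% had the same sign (64.6% in the simulations) and Pearson's r across genes, which are not independent replicates, was 0.66 (0.43 in the simulations). The covariance was 0.07 (0.0715) against 0.0158 in the simulations, a difference of 0.0557. The 3 controls were too few to split, so part of the excess over the expected overlap may come from the shared controls.

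**Figure D3:**
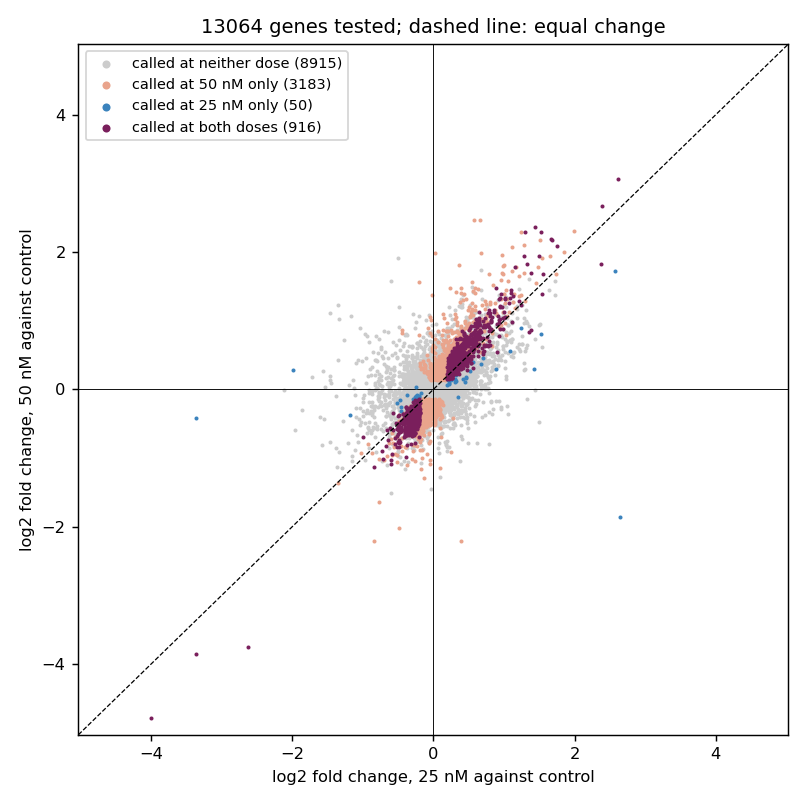
Log2 fold change at 50 nM (vertical axis) against that at 25 nM (horizontal axis) for 13064 genes, coloured by the dose at which they were called, with a dashed line of equal change. Of these, 916 were called at both doses, 3183 at 50 nM alone and 50 at 25 nM alone. The control libraries are shared by both axes.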

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

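The length and GC correction, the comparison of length slopes between libraries and the tests of BOLA2 and BOLA2B below were tests chosen after the results had been seen.

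Cytosolic ribosomal proteins differed between the doses, with a median of −0.091 at 50 nM against 25 nM (adjusted p = 0.000889, but adjusted p = 0.221 with an estimated correlation), although against control neither dose was called. Mitochondrially encoded mRNAs also differed between the doses (median 0.318, adjusted p = 4.04e-07, but adjusted p = 0.235 with an estimated correlation), and this call ended without 25 nM replicate 2 (adjusted p = 0.353), the library with the lowest mitochondrial share.

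Long transcripts were higher and short ones lower at 50 nM. Length slopes were fitted, beside GC content, to each library's log2 CPM less the gene's mean over the 8 libraries. Their sign is thus relative to the other libraries. They were −0.0322 to −0.0299 per doubling of length in control libraries and 0.0295 to 0.0413 at 50 nM. The gap was 0.0594, against a largest range of 0.0118 within a group, which argues against a bias that varied between libraries regardless of group. The 25 nM libraries had slopes of −0.00872 and −0.00651, between those of control and 50 nM. The slopes were thus ordered by dose, and the other 2 contrasts carry part of the trend. It was also asked whether short-transcript gene classes that fell made the trend. Every gene of the fixed lists, risen, fallen or not called, and further ribosomal, proteasome and respiratory chain families were therefore left out. The length slope of the log2 fold change at 50 nM was then 0.0641 over the remaining 8965 genes, against 0.0668 over 9792. The trend was thus not confined to the genes left out, and other short classes were not tested. The labels record no batch, so a difference in RNA or library preparation that followed the groups could produce this gap of 0.0594 as well as a change in the cells could.

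BOLA2 and BOLA2B were lower at both doses. If reads had moved between these near-identical copies, their sum would have stayed level, but in control replicate 3 the summed count was 26.2 times that of the higher of the other control libraries. Without control replicate 3, 0 of the 2 genes passed both thresholds, so the fall rested on a single library; why that library differed was not tested.

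With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real grouping was the 1 split with the most called genes (4388, highest other 0) and the most over 2-fold (148, highest other 0). It also had the most called lists (20). The other splits called 7 to 16 lists although they had 0 called genes, so lists can be called where no gene is. Each other split set treated and control libraries together on both sides, so part of any treatment difference remained in it, and these splits do not show what unchanged groups would give.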

How the results depend on the processing

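No named gene changed direction while called under any alternative, and DESeq2 size factors left every list call as it was. At 50 nM against control the calls over 2-fold went from 145 higher and 23 lower to 42 and 6 with genes of at least 5 CPM (fewer genes tested). With DESeq2 they were 79 and 15, with 1269 genes left without an adjusted p. The lower ones went to 14 after the length and GC correction, chosen after seeing the data. At 25 nM the calls over 2-fold went from 36 and 7 to 18 and 1 with genes of at least 5 CPM. DESeq2 gave 19 and 1, with 2788 genes left without an adjusted p, and no filter gave 13 lower. The length and GC correction gave 1005 lower genes in all, against 428. Between doses, against 156 higher and 377 lower, the counts were 244 and 601 without a filter, 93 and 227 with only the libraries of the groups compared (fewer samples), and 84 and 165 after the length and GC correction. With an estimated correlation 13, 13 and 0 lists were called, and with fry 21, 22 and 12, against 20, 20 and 14. Genes shared by the doses came to 30 with a 2-fold limit as well, against 916. Leaving out each library in turn gave 344 (without control replicate 2) to 604 higher (without 50 nM replicate 1) and 168 to 544 lower genes at 25 nM, on the same omissions. Between doses it gave 29 (without 50 nM replicate 2) to 151 higher and 93 to 380 lower genes (highest without control replicate 3), and 8 (without 25 nM replicate 2) to 15 called lists (without control replicate 1 or 50 nM replicate 1). Mitochondrially encoded mRNAs at 25 nM against control reversed sign with 1 library left at that dose. Their median was −0.43 without 25 nM replicate 1 and 0.17 without 25 nM replicate 2. The same replicate numbers did not pair libraries (7 correlations of −0.06 to 0.045); with the number as a block 1902 and 2227, 494 and 339, and 222 and 515 genes were called. Where no reason is given, the cause was not tested.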

Other observations

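The further HIF targets below were listed after the ranking of genes had been seen but before their own values were looked up; the other tests were chosen after the results had been seen.

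Of 28 measured further targets of the hypoxia-inducible factors, outside the list tested in the report, 19 were higher and 0 lower at 50 nM (median 0.40), and 11 and 0 at 25 nM (median 0.28). BHLHE40, a transcriptional repressor, rose by 2.30 ± 0.18 at 50 nM and 1.52 ± 0.21 at 25 nM, the histone demethylase gene KDM3A by 0.93 ± 0.06 and 0.74 ± 0.07, and AK4, a mitochondrial adenylate kinase, by 1.01 ± 0.09 and 0.65 ± 0.10. HILPDA, a lipid droplet gene induced by hypoxia, was not called and its estimate was negative (−0.16 ± 0.10, adjusted p = 0.275), as were those of QSOX1 and SAP30. MIR210HG, the host transcript of a hypoxia-induced microRNA, named after its values were seen, rose 8.35-fold at 50 nM (3.06 ± 0.16, adjusted p = 1.39e-11) and 6.16-fold at 25 nM.

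Sterol and hypoxia genes rose together, for which a technical trend and biological causes were weighed. After the length and GC trend was removed, the median of the 48 members of both lists together was 0.635 (bootstrap 95% interval 0.412 to 0.824). It was 0.589 before, so that trend does not account for the rise. The members are not independent replicates, so this interval is only descriptive. As given above, each list was also called higher on its own after that removal. HIF activity may contribute to the hypoxia part, since 67.9% of its further targets were higher at 50 nM against 14.4% of other genes (one-sided Fisher exact p = 2.14e-10). Fisher's test takes genes as independent, and the list was written after the ranking had been seen, so this p-value is only descriptive. The share of 14.4% was not matched for transcript length, and among genes over 4000 nt 26.7% were higher. Low iron would stabilise HIF and raise TFRC, which rose by 0.405, but TFRC is itself a HIF target and SLC11A2 and CDC14A, the other measured transcripts with a 3' iron-responsive element, were not called, so this test does not separate low iron from HIF activity. For impaired lysosomal acidification with TFEB activity, a rise of the V-ATPase subunit transcripts was predicted. That rise was not seen (median 0.06, 0 of 16 higher, ATP6V0B and ATP6V0E2 lower), although FNIP1, RRAGD, FLCN and MAP1LC3B rose. Subunit transcripts do not measure acidity or V-ATPase function, so this test cannot decide whether acidification was impaired.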
